A study of Mus musculus with 12 samples.

How the data were processed

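RNA was measured by bulk sequencing of sorted live CD45.2+ cells in 12 libraries, 3 in each of 4 groups, from a stranded total RNA library kit. Each library was placed in its group by the sample titles, which also give the replicate number. The labels also give a batch for each library. Libraries with the same replicate number in the CTRL and ATRA groups of a state share a batch, and the libraries without and with restimulation come from different batch sets, so batch set and state cannot be told apart. The labels do not say whether the libraries of a group came from separate mice or cultures, so p-values measure only the spread between these libraries.

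The authors deposited 2 tables of whole-number counts per gene symbol, 1 for each state, and 1 table of TPM (transcript abundance relative to the library total) for the restimulated libraries. Per the submitters' processing notes, cutadapt 5.0, STAR 2.7.11b, Salmon 1.10.3, DESeq2 1.42.1 and the mouse build mm39 were used. The role of each tool, the strand setting and the gene annotation are not given in the sources used here. The deposited count table without restimulation held 13948 genes, and its smallest row sum was 10. The deposited count table with restimulation held 35588 rows, of which 16386 were 0 in all 6 libraries and 32 repeated the symbol of another row; the row with the largest total kept the symbol. The deposited TPM table held 35682 rows. Its column headings differ from those that the labels give and show the treatment but neither the state nor the library. The labels assign the table to the restimulated samples, so its columns were used as replicates of their group, with no number or pairing. The 2 count tables had 13611 symbols in common and differed in naming, for example in mitochondrial and ATP synthase genes, which were matched by their synonyms only for the mitochondrial list. Total counts were 23558244 to 26111497 per library without restimulation and 16288111 to 20115836 with it. At the lowest total, 3 counts correspond to 0.184 CPM (counts scaled to the library total), and this floor covers counting error only. No coordinates are given, because no reference of build mm39 was used.

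Replicates were compared before they were averaged. Pearson correlations of log CPM across genes were 0.978 to 0.994 between CTRL libraries without restimulation and 0.976 to 0.984 between libraries within each restimulated group. Between ATRA libraries without restimulation the correlation was 0.990 for replicates 1 and 2 and 0.948 and 0.962 for replicate 3 against them. No 2 libraries were alike within sampling noise, since the smallest chi-square per degree of freedom between libraries of a group was 3.86. Because the labels state a shared batch, the replicate numbers pair the libraries. In the check of that pairing, deviations of same-numbered libraries from their group means correlated at 0.13, -0.06 and 0.07 without restimulation and at -0.03, -0.09 and 0.04 with it, and the replicate block left 2892 called genes without restimulation and 7752 with it.

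Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group, quasi-likelihood fits with robust estimation and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. ATRA was compared with CTRL within each state on the 6 libraries of that state. The difference between these effects was tested as an interaction on all 12 libraries and the genes in both tables. Restimulated and other control cells were compared in a secondary fit. Shared effects were counted as genes called in both ATRA comparisons. The comparisons of the ATRA effect use separate controls. Levels are TMM-scaled CPM as mean ± SD over 3 libraries. They were scaled within each table, so a level set across the tables is a description. Folds against a group at 0 in every library are lower bounds against 3 counts in each library, on the scale of the fitted genes. Standard errors of log2 fold changes (SE) were computed from the coefficient and its quasi-likelihood F.

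Lists of genes for 22 pathways and 7 other cell types were tested with camera of limma 3.58.1, with a preset correlation of 0.01, where at least 5 members were tested; camera with an estimated correlation and fry were alternatives. Named genes followed a rule. For each ATRA comparison it took the 6 largest called changes in each direction with a mean of at least 5 CPM and no overlap between groups, leaving out predicted and clone-named genes, the 2 called members with the smallest p in each list, and 24 genes fixed by name. For the interaction and for restimulation it took the 5 largest in each direction, and for the interaction the absence of overlap was asked for within both states. The groups, tests, lists, rule and alternatives were chosen before the data were examined, except this reading of overlap for the interaction. Other alternatives are named as added where they are given. Il2, Rarb and Cyp26b1, among the 24 fixed genes, did not pass the filter in any comparison. Some genes named by the rule are not reported here.

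The alternatives were RLE, upper-quartile and library-total scaling, other filters on low counts, DESeq2 1.42.0, limma-voom, a further threshold of 2-fold, the replicate block, a fit of all 12 libraries, leaving out each library in turn, and limma on log2(TPM + 1) or log2(TPM + 0.1) from the deposited TPM table. All columns of the tables were used. Fits were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. Far more genes were called in the real comparisons, so the shares recovered and falsely called need not carry over to them. Without restimulation, edgeR recovered 5.97% of genes changed 1.5-fold, 40.3% of those changed 2-fold and 87.9% of those changed 4-fold among 12111 genes, and 7.29% of its calls were unchanged genes. With restimulation it recovered 53.7%, 74.6% and 90.9% of them among 12792 genes, and 13.1% of its calls were unchanged genes. For the interaction it recovered 1.49%, 38.8% and 89.4% among 12359 genes, and 6.52% of its calls were unchanged genes. For restimulation of control cells it recovered 43.3%, 80.6% and 95.5% among 11645 genes, and 5.19% of its calls were unchanged genes. In the simulated comparisons of ATRA, camera called the 1 shifted list of 20 and 0 of the others, while fry also called 1 unshifted list without restimulation. Simulated genes varied independently of each other, so these list results do not test the effect of correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.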

Results

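Gene expression was measured in OT-I CD8+ T cells, cytotoxic T lymphocytes of transgenic mice whose T cell receptor recognises a peptide of chicken ovalbumin. Spleen cells were activated with antibodies against CD3e and CD28 plus IL-2, either in the presence of ATRA (all-trans retinoic acid, the vitamin A metabolite that binds nuclear retinoic acid receptors) at 5 ng/mL or with its solvent DMSO (CTRL). After 5 more days in culture they were exposed for 72 h at 1% oxygen to GL261, a mouse glioma line carrying ovalbumin, a setting meant to drive exhaustion, and no ATRA was added in that phase. Cells were sorted at that point or after 24 h of restimulation through CD3e. Each of the 4 groups had 3 libraries, with 23558244 to 26111497 counts per library before restimulation and 16288111 to 20115836 after it.

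The first comparison asked how prior exposure to ATRA altered T cells at the end of the co-culture. The gut homing receptor genes Ccr9, Itgb7 and Itga4 were higher in ATRA cells. Ccr9, the chemokine receptor for small intestinal homing, stood at 40.9 ± 0.949 CPM (SD, n = 3) in ATRA cells and at 0 in all 3 control libraries, at least 363-fold higher (adjusted p = 0.000181). Itgb7, the beta7 integrin chain, rose from 47.7 ± 0.897 to 544 ± 110 CPM, and its partner Itga4 rose from 106 ± 14.2 to 264 ± 42.5 CPM. Ifng, which encodes interferon gamma, fell from 727 ± 110 to 51.5 ± 36.6 CPM, and Xcl1, a chemokine that attracts cross-presenting dendritic cells, fell from 437 ± 121 to 1.02 ± 0.477 CPM. Pdcd1, which encodes the inhibitory receptor PD-1, fell from 124 ± 28.6 to 15.2 ± 10.5 CPM.

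In all, 4071 of 12111 tested genes were called, 2188 higher and 1883 lower in ATRA cells, and 1826 of them by at least 2-fold. The libraries of the 2 groups did not overlap for 6905 genes (57.0%), where chance gives 10%. Among the largest increases were Sorcs2, a sorting receptor of the nervous system, at least 299.6-fold higher, and Grhl3, an epithelial transcription factor (log2 fold change 8.52, SE 1.52), whose level was 11.0 ± 12.3 CPM in ATRA cells and whose log2 fold change was 7.08 without ATRA replicate 3. P2rx7, the receptor for extracellular ATP, rose from 0.354 ± 0.068 to 67.3 ± 11.4 CPM. Tgm2, the retinoid-inducible transglutaminase, rose from 0.277 ± 0.022 to 50.0 ± 5.59 CPM. Acvrl1, a receptor of the TGF-beta family, rose by a log2 fold change of 7.40 (SE 0.42). The largest decreases, next to Xcl1, were those of Slc6a12, a betaine and GABA transporter (at least 90.0-fold lower), Actbl2, a beta-actin-like gene (-9.18, SE 0.57), Tm4sf19 (-8.37, SE 0.43), and Ugt1a5 and Ugt1a9, glucuronidating enzymes (-8.07 and -8.03). Ugt1a5 and Ugt1a9 share exons in 1 gene cluster, so their counts are uncertain between them. Leaving out 1 library also moved Acvrl1 to 8.32 (CTRL replicate 2), Actbl2 to -9.87 and Ugt1a5 to -11.32 (ATRA replicate 2), and Tm4sf19 to -9.50 and Ugt1a9 to -9.08 (ATRA replicate 1). The Slc6a12 call ended without CTRL replicate 2 (adjusted p = 0.0601) or CTRL replicate 3 (adjusted p = 0.0653). The number of called genes fell to 1772 without CTRL replicate 2, to 1613 without CTRL replicate 3 and to 2226 without ATRA replicate 2. It was 7980 without CTRL replicate 1 and ATRA replicate 3, the libraries that stood apart from their groups, an alternative added after the data were seen that narrows the spread by its construction.

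The fixed list of cytokines and chemokines moved down. Of 23 tested members 12 fell and 3 rose, with 12 and 4 adjusted over the list alone (camera adjusted p = 1.2e-05, and adjusted p = 0.283 with an estimated correlation). Ccl9 fell by 7.95 (-8.85 without ATRA replicate 3) and the inflammatory chemokine genes Ccl3 and Ccl4 each fell by 4.69 on the log2 scale. Il4, the cytokine of type 2 responses, rose instead by 6.72, from 0.049 ± 0.056 to 5.74 ± 6.82 CPM. Its SD in ATRA cells was above its mean. Among 21 cytotoxic effector genes 9 fell and 4 rose, as they did adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.552 with an estimated correlation). Prf1, which encodes perforin, fell from 743 ± 106 to 267 ± 3.73 CPM and Tbx21, the T-bet transcription factor, from 121 ± 6.33 to 46.6 ± 6.90 CPM, while Gzma rose by 1.15. Gzmb, which encodes granzyme B, stood at 1376 ± 286 in CTRL and 1298 ± 281 CPM in ATRA cells (adjusted p = 0.806), and Tnf at 132 ± 20.6 and 82.1 ± 41.7 CPM (adjusted p = 0.223). Of 30 genes induced by T cell activation 9 fell and 5 rose, with 10 and 6 adjusted over the list alone (camera adjusted p = 0.0613). The list passed with the replicate block (adjusted p = 0.0302) and without CTRL replicate 2 (0.0277), CTRL replicate 3 (0.0391) or ATRA replicate 3 (0.0430). Egr2, a transcription factor induced by T cell receptor signals, fell from 199 ± 30.8 to 4.69 ± 0.658 CPM, and Nr4a2, an orphan nuclear receptor of the same kind of response, from 165 ± 61.9 to 21.2 ± 5.67 CPM.

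Genes induced by low oxygen were higher in ATRA cells, although both groups were kept at 1% oxygen. Of 24 hypoxia response genes 22 rose and 0 fell, with 23 and 0 adjusted over the list alone (camera adjusted p = 2.5e-20, and adjusted p = 0.530 with an estimated correlation). Zfp395 rose from 7.45 ± 1.64 to 123 ± 19.4 CPM, Ndrg1, a stress-responsive differentiation gene, from 37.0 ± 0.652 to 422 ± 127 CPM, and Vegfa, the vascular growth factor, by a log2 fold change of 2.03. Of 21 glycolysis genes 16 rose and 0 fell, with 19 and 0 adjusted over the list alone (camera adjusted p = 1.1e-06, and adjusted p = 0.552 with an estimated correlation). Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose from 87.4 ± 3.47 to 173 ± 19.3 CPM and Pfkfb3, an activator of phosphofructokinase, from 41.2 ± 0.499 to 117 ± 25.3 CPM. In contrast, 15 of 31 genes of cholesterol and fatty acid synthesis fell and 2 rose, with 17 and 3 adjusted over the list alone (camera adjusted p = 0.000198, and adjusted p = 0.552 with an estimated correlation). Idi1 and Cyp51, enzymes of the cholesterol pathway, fell from 64.2 ± 1.88 to 23.4 ± 1.29 CPM and from 225 ± 7.66 to 93.5 ± 7.96 CPM. The cholesterol exporter gene Abcg1 and Mylip, which marks the LDL receptor for degradation, rose by 1.45 and 2.71. Of 38 nuclear genes of oxidative phosphorylation 6 fell and 1 rose, with 4 and 1 adjusted over the list alone, among them Sdhb (-0.53) and Atp5f1d (0.56), and 0 of 13 mitochondrially encoded genes passed either way (camera adjusted p = 0.367 and 0.906). The mitochondrial list had a median of -0.04 and a mean of 0.09, and its test pointed up.

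Of 19 trafficking receptors 9 rose and 3 fell, with 10 and 3 adjusted over the list alone (camera adjusted p = 7.7e-06, and adjusted p = 0.239 with an estimated correlation). S1pr1, the receptor for exit from lymphoid tissue, rose from 14.8 ± 2.12 to 69.6 ± 11.3 CPM. Of 22 TGF-beta and tissue residency genes 9 rose and 2 fell, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.00171, and adjusted p = 0.552 with an estimated correlation), but the risers included S1pr1 and Klf2 (4.29), which are known for circulating rather than resident cells. Of 19 MHC and antigen processing genes 11 rose and 1 fell, with 13 and 1 adjusted over the list alone (camera adjusted p = 0.00177, and adjusted p = 0.552 with an estimated correlation). H2-Q4, a class I gene of a family of close copies, rose by 1.61 and H2-Ab1, a class II gene, by 2.30, while Cd74, the class II invariant chain, fell by 1.30. Dendritic cell markers, some of which are also MHC class II genes, summed to 122 to 139 CPM in CTRL and 234 to 286 CPM in ATRA libraries. Of 12 tested retinoic acid response genes 4 rose and 2 fell, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.0907). The retinoic acid receptor gene Rara rose from 17.0 ± 2.23 to 47.8 ± 8.90 CPM, whereas Crabp2, a retinoic acid binding protein, fell from 37.4 ± 4.21 to 0.737 ± 0.232 CPM.

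The exhaustion and memory lists were mixed. Of 17 inhibitory receptors 7 rose and 6 fell, with 7 and 8 adjusted over the list alone, and their median (-0.18) and mean (-0.04) differed in sign from the upward direction of the test (camera adjusted p = 0.607). Tigit fell from 108 ± 4.25 to 49.0 ± 2.09 CPM, while Pecam1 rose by 2.25 and Entpd1, which encodes the ectonucleotidase CD39, rose from 34.6 ± 2.22 to 86.9 ± 9.77 CPM. Lag3 (0.11), Havcr2 (-0.65), which encodes TIM-3, and Tox (-1.68), a transcription factor of exhausted T cells, did not pass (adjusted p = 0.646, 0.0812 and 0.205). Of 25 terminal exhaustion genes 9 fell and 6 rose, with 11 and 9 adjusted over the list alone (camera adjusted p = 0.211). Eomes, a T-box transcription factor, fell from 27.2 ± 4.47 to 9.25 ± 0.485 CPM. Of 21 progenitor and memory genes 9 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0841). Tcf7 and Slamf6, markers of progenitor exhausted cells, had log2 fold changes of 1.41 and 0.88 that did not pass (adjusted p = 0.133 and 0.0839). Without ATRA replicate 3, which stood apart from the other ATRA libraries, both passed (adjusted p = 0.00558 and 0.00279), as did Tox (-1.10, adjusted p = 0.0263) and Havcr2 (-0.93, adjusted p = 0.00585), and so did the terminal exhaustion (adjusted p = 0.00156) and memory lists (adjusted p = 0.00685). The memory list also passed without CTRL replicate 1 (adjusted p = 0.0366).

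Among further lists, 4 of 34 cell cycle genes fell and 0 rose (camera adjusted p = 0.000311, and adjusted p = 0.746 with an estimated correlation), and 1 of 27 replication histone genes rose and 1 fell (camera adjusted p = 0.0115, and adjusted p = 0.793 with an estimated correlation). Adjusted over the list alone, 0 genes of either passed. Of 37 interferon response genes 2 rose and 0 fell, with 0 adjusted over the list alone (camera adjusted p = 0.163). That list passed with the replicate block (adjusted p = 0.0383) and without CTRL replicate 1 (0.00244) or ATRA replicate 3 (0.000168). Without both of these libraries, an alternative added after the data were seen, its adjusted p was 5.3e-21 and the replication histone list lost its call (adjusted p = 0.0544). Isg20 had 338 counts in CTRL replicate 1, against 124 and 114, and 493 in ATRA replicate 3, against 1333 and 1112. Rsad2 had the same order. Leaving out these libraries thus also widened the difference in these genes, so the small p depends on that choice. Of 24 p53 target and apoptosis genes 8 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0823, and 0.0440 without CTRL replicate 1), among them Cdkn1a, the p21 cell cycle inhibitor (0.98), and Trp53inp1 (2.13). Of 30 genes of the unfolded protein and integrated stress responses 3 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.742), with Vldlr at 2.84 and Atf5 at 1.59. Of 22 T cell receptor complex and signalling genes 4 rose and 6 fell, with 5 and 7 adjusted over the list alone (camera adjusted p = 0.521). Cd5, a negative regulator of that receptor, fell by 1.20 and the adaptor gene Lcp2 fell by 0.95. Of 20 heat shock and stress genes 5 rose and 2 fell, with 5 and 3 adjusted over the list alone (camera adjusted p = 0.163), and the chaperone genes Hspa1a and Hspb1 rose by 5.02 (4.37 without ATRA replicate 3) and 3.21.

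Several calls in this comparison ended when 1 library was left out, which also lowers the number of libraries in the test, while the log2 fold changes kept their direction. The proliferation gene Mki67 fell from 1717 ± 45.7 to 930 ± 332 CPM (adjusted p = 0.0453), but its call ended with the replicate block (adjusted p = 0.0535) and without any CTRL library or ATRA replicate 2 (adjusted p = 0.0810 to 0.124), where its log2 fold change of -0.88 became -0.99 to -0.86. Ccne2, a cyclin gene at -1.45, lost its call without any of the same libraries (-1.57 to -1.42, adjusted p = 0.0574 to 0.0749). Without CTRL replicate 2 or 3, the calls of Ccne1 (-0.97, adjusted p = 0.0663 and 0.0699) and Il7r, the interleukin 7 receptor gene (1.12, adjusted p = 0.0581 and 0.0663), ended. Itgae, which encodes the CD103 integrin, rose by 3.47, a call that ended without any 1 of the CTRL libraries (3.29 to 3.72, adjusted p = 0.0810 to 0.0969). Its level was 7.84 ± 8.42 CPM in ATRA cells, and without ATRA replicate 3 its log2 fold change was 2.10 (adjusted p = 0.0132). The calls of Isg20 (2.45, adjusted p = 0.0522 to 0.0704) and H4c9 (0.62, adjusted p = 0.0853 to 0.122) ended without CTRL replicates 2 or 3 or ATRA replicate 2. Rsad2 (2.85, adjusted p = 0.0759 to 0.125) lost its call without those or ATRA replicate 1, and H2ac6 (-0.43, adjusted p = 0.0580 to 0.135) without any library but ATRA replicate 3. Without CTRL replicate 1, Isg20 and Rsad2 stood at 3.18 and 3.92. With the replicate block, H4c9 and H2ac6 stood at adjusted p = 0.0712 and 0.0912.

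Markers of other cell types moved both ways in the cells sorted after co-culture. GL261-like genes summed to 140 to 171 CPM in CTRL and 96.7 to 105 CPM in ATRA libraries, with 4 of 8 tested members higher and 3 lower (camera adjusted p = 0.797), and 4 and 4 adjusted over the list alone. Axl alone gave 95.7 to 122 CPM of these sums in CTRL libraries and 59.4 and 48.9 CPM in ATRA replicates 1 and 2. Igfbp7 fell from 29.8 ± 7.71 to 0.503 ± 0.186 CPM and Loxl2 rose from 3.64 ± 1.19 to 31.8 ± 6.51 CPM. Of 9 dendritic cell genes 3 rose and 2 fell (camera adjusted p = 0.731), with Zbtb46 at -2.70, of 7 NK cell genes 2 rose and 2 fell, where the median (1.08) and mean (0.03) were above 0 and the test pointed down (camera adjusted p = 0.906), and of 9 CD4 T cell genes 2 rose and 4 fell (camera adjusted p = 0.521), with Zbtb7b at 0.84. Among 3 tested B cell genes (median 0.09, mean -0.04) Cd79b rose by 1.90 and Ebf1 fell by 2.13, and among 3 monocyte and macrophage genes Cd68 and Itgam rose by 0.84 and 2.79 and Cd14 fell by 2.15. These counts were the same adjusted over the list alone. The Ebf1 call ended without CTRL replicates 2 or 3 or ATRA replicate 2 (adjusted p = 0.0609 to 0.0754). Without CTRL replicate 2 the calls of Itgam and of Klre1, an NK receptor gene (-4.06), ended (adjusted p = 0.0527 and 0.0521), and without ATRA replicate 1 Klre1 stood at -4.92. No erythroid gene passed the filter. ATRA replicate 3 differed from the other ATRA libraries in several of these genes, with Gzma at 1085 against 457 and 573 CPM and Gata3 at 126 CPM.

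**Figure D1:**
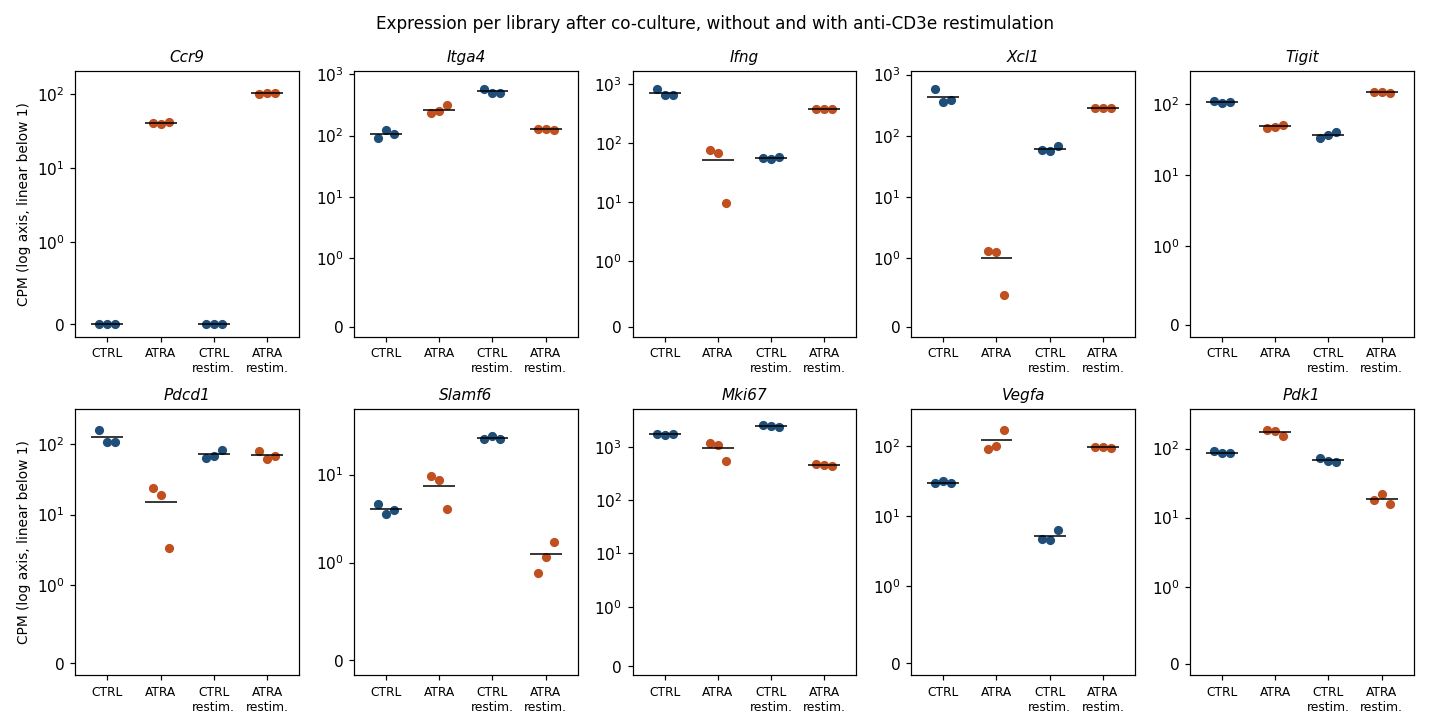
Expression of 10 named genes in each library as CPM on an axis that is logarithmic above 1 and linear below it, for the 4 groups of 3 libraries; points are libraries and horizontal lines are group means. Ccr9 stood at 0 in all CTRL libraries, and Ifng, Xcl1, Tigit and Itga4 differed between CTRL and ATRA in opposite directions before and after restimulation.

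The second comparison asked how the same ATRA exposure altered the response of co-cultured cells to 24 h of CD3e restimulation. Cytokine genes were higher in ATRA cells, with 21 of 24 listed members rising and 1 falling. Ifng rose from 56.7 ± 2.80 CPM in CTRL to 384 ± 4.92 CPM, Il3, a haematopoietic growth factor, from 0.241 ± 0.166 to 117 ± 5.81 CPM, and Il5, the eosinophil growth factor, from 0.191 ± 0.087 to 66.8 ± 2.39 CPM. Cell cycle genes were lower, with all 34 listed members falling, and the proliferation gene Mki67 fell from 2470 ± 85.2 to 454 ± 17.7 CPM (adjusted p = 5.4e-11). Ccr9 again had no counts in CTRL and stood at 102 ± 1.90 CPM in ATRA cells, at least 602-fold higher. Itga4 fell from 523 ± 38.4 to 126 ± 1.01 CPM, while Itgb7 did not pass (226 ± 41.2 and 241 ± 5.36 CPM, adjusted p = 0.490).

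Of 12792 tested genes 7998 were called, 4068 higher and 3930 lower in ATRA cells, and 3287 of them by at least 2-fold. The groups did not overlap for 8796 genes (68.8%), where chance gives 10%. With all control libraries at 0, the stefin genes Stfa2 and Stfa3, which are close copies whose counts are uncertain between them, were at least 369.6-fold and at least 75.9-fold higher. Ptgs2, which encodes the prostaglandin enzyme COX-2, and Mmp13, a collagenase, were at least 202.5-fold and at least 113-fold higher. Il4 rose by a log2 fold change of 11.40 (SE 0.29) from 0.018 ± 0.031 to 69.6 ± 5.89 CPM. Dscam, a neuronal adhesion molecule, was at least 65.6-fold lower. Other large decreases on the log2 scale were those of Trp73, a p53 family member (-6.39), the ciliary gene Cfap91 (-6.35), the inhibitory lectin receptor gene Clec12a (-6.32) and the sialic acid hydroxylase gene Cmah (-6.15). Leaving out 1 library moved Il4 to 13.31 and Il3 from 8.86 to 9.57 (CTRL replicate 3), Trp73 to -7.24 (ATRA replicate 2), Cfap91 to -8.54 (ATRA replicate 1) or -5.75 (ATRA replicate 3) and Cmah to -6.87 (ATRA replicate 3). Sema4a, a semaphorin expressed in T cells, fell from 116 ± 12.9 to 1.67 ± 0.326 CPM.

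Of 24 cytokine and chemokine genes 21 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 1.4e-26, and adjusted p = 0.00496 with an estimated correlation). The exception was Ltb, a lymphoid tissue cytokine (-3.12). Tnf rose from 32.8 ± 2.71 to 66.6 ± 1.26 CPM and Xcl1 from 60.8 ± 6.34 to 285 ± 1.38 CPM. Of 30 activation genes 25 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 2.6e-14, and adjusted p = 0.0453 with an estimated correlation). Egr1 rose from 35.2 ± 1.28 to 210 ± 5.24 CPM and Tnfrsf9, which encodes the costimulatory receptor 4-1BB, from 96.0 ± 2.79 to 397 ± 13.3 CPM, whereas Myc fell by 1.67. Among 21 cytotoxic effector genes 9 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.225, and 0.000269 without CTRL replicate 3). Prf1 rose from 136 ± 11.1 to 394 ± 6.48 CPM and Gzmb from 754 ± 46.2 to 1097 ± 23.9 CPM, while Klrk1, which encodes the activating receptor NKG2D, fell from 120 ± 11.1 to 17.0 ± 2.05 CPM. Beside these lists, 4 of 7 CD4 T cell genes rose and 0 fell (camera adjusted p = 0.0130, and adjusted p = 0.241 with an estimated correlation), namely Il4, Il17a, Izumo1r and Gata3, which rose from 62.6 ± 8.26 to 116 ± 4.11 CPM. That count was the same adjusted over the list alone, and Il4 and Il17a also belong to the cytokine list. The CD4 markers summed to 78.3 to 98.2 CPM in CTRL and 220 to 228 CPM in ATRA libraries.

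All 34 cell cycle genes fell, also adjusted over the list alone (camera adjusted p = 2.4e-53, and adjusted p = 0.00149 with an estimated correlation). Kif20a, a kinesin of cell division, fell from 229 ± 2.13 to 39.4 ± 1.92 CPM. Of 27 replication histone genes 26 fell and 1, H1f2, rose, also adjusted over the list alone (camera adjusted p = 2.6e-14, and adjusted p = 0.267 with an estimated correlation). H3c8 fell by 2.08 and H1f5 fell by 2.60. Of 30 genes of the unfolded protein and integrated stress responses 26 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 3.4e-13, and adjusted p = 0.0411 with an estimated correlation). Slc3a2, an amino acid transporter subunit, rose from 176 ± 5.70 to 831 ± 25.2 CPM and Atf4, the transcription factor of the integrated stress response, by a log2 fold change of 2.11. Of 25 p53 target and apoptosis genes 14 rose and 5 fell, with 15 and 5 adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.241 with an estimated correlation), with Plk2 rising by 2.87 and Ckap2 falling by 2.03. Of 20 heat shock and stress genes 11 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.000211, and adjusted p = 0.0817 with an estimated correlation). The risers were Fos (3.64), Fosb, Jun, Egr1, Atf3, Ier2, Dusp1 and Zfp36, an mRNA decay factor (2.74), which are immediate early or stress-induced genes, and the chaperone-related Hsph1, Dnaja1 and Bag3, while the chaperone genes Hspd1 and Hspe1 fell.

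Of 18 inhibitory receptors 9 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0306, and adjusted p = 0.546 with an estimated correlation), and the list call ended without CTRL replicate 1 (adjusted p = 0.0559). Tigit rose from 37.2 ± 3.46 to 147 ± 2.26 CPM, Havcr2 from 118 ± 23.7 to 255 ± 5.65 CPM, Lag3 from 81.6 ± 29.4 to 218 ± 5.62 CPM and Vsir, which encodes VISTA, by 1.28. Pdcd1 stood at 71.5 ± 10.9 and 69.6 ± 8.56 CPM (adjusted p = 0.829) and Entpd1 at 27.8 ± 11.9 and 31.0 ± 1.75 CPM (adjusted p = 0.644), and without CTRL replicate 3 Entpd1 (0.56, adjusted p = 0.00169) passed. Of 26 terminal exhaustion genes 14 rose and 4 fell, with 15 and 4 adjusted over the list alone (camera adjusted p = 0.000305, and adjusted p = 0.205 with an estimated correlation). Ccl3 rose by 3.18 and Rgs16, a regulator of G protein signalling, by 2.16, while Tox did not pass (-0.23, adjusted p = 0.752). Of 20 progenitor and memory genes 9 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.452). Slamf6 fell from 26.2 ± 1.38 to 1.25 ± 0.411 CPM, whereas Satb1, a chromatin organiser, rose from 110 ± 10.9 to 592 ± 18.5 CPM. Tcf7 (-2.83, adjusted p = 0.0839) and Il7r (-0.09, adjusted p = 0.585) did not pass. Tcf7 passed without CTRL replicate 1 (adjusted p = 0.0495) or 2 (adjusted p = 0.0246), but its fold rested on CTRL replicate 3, without which it was -0.65 (adjusted p = 0.471). Il7r passed without CTRL replicate 2 (-0.24, adjusted p = 0.0467).

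Of 21 trafficking receptors 12 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.0201, and adjusted p = 0.440 with an estimated correlation), and the list call ended without CTRL replicate 3 (adjusted p = 0.221). Itgb7 passed without that library (0.24, adjusted p = 0.0134). S1pr1 fell from 77.6 ± 5.17 to 8.22 ± 0.594 CPM. Itgae (0.65, adjusted p = 0.0383) lost its call without CTRL replicate 1 or 2 or ATRA replicate 2 or 3 (adjusted p = 0.0971 to 0.131). Of 22 TGF-beta and tissue residency genes 11 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.0164, and adjusted p = 0.357 with an estimated correlation), with Rgs2 rising by 4.39, and this call ended without CTRL replicate 1 (adjusted p = 0.0543). Of 14 retinoic acid response genes 10 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.00944, and adjusted p = 0.139 with an estimated correlation). Crabp2 rose from 1.73 ± 0.617 to 33.1 ± 2.54 CPM, Stra6, the retinol uptake receptor gene, from 2.45 ± 0.583 to 34.0 ± 0.983 CPM and Rara by 0.53, whereas Dhrs3, a retinal reductase gene, fell by 1.64.

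Metabolic lists were mixed after restimulation. Of 22 hypoxia response genes 12 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.000191, and adjusted p = 0.127 with an estimated correlation). Vegfa rose from 5.14 ± 1.00 to 95.7 ± 2.11 CPM and Nupr1, a stress-induced nuclear protein gene, from 0.620 ± 0.167 to 34.6 ± 0.467 CPM, while Zfp395 fell by 1.49. Of 21 glycolysis genes 7 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.557). Pdk1 fell from 68.0 ± 5.11 to 18.7 ± 3.37 CPM and the glucose transporter gene Slc2a1 rose from 69.1 ± 3.31 to 124 ± 1.46 CPM. Of 31 cholesterol and fatty acid genes 22 fell and 2 rose, with 22 and 3 adjusted over the list alone (camera adjusted p = 6.7e-05, and adjusted p = 0.321 with an estimated correlation). The desaturase gene Fads1 fell by 2.31 and the carboxylase gene Acaca fell by 1.68. Of 38 nuclear oxidative phosphorylation genes 18 fell and 9 rose, with 19 and 10 adjusted over the list alone (camera adjusted p = 0.355), with Ndufb10 at -0.74. Of 13 mitochondrially encoded genes 9 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.225), with mt-Nd4 at 0.40 and mt-Co2 at 0.38.

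Interferon genes split, with 14 of 32 rising and 8 falling, and 14 and 9 adjusted over the list alone. The test pointed down, as did the mean (-0.01), while the median was 0.11 (camera adjusted p = 0.805). Oas3 (-2.90), an antiviral enzyme gene, and Gbp3 (-1.87), a guanylate binding protein gene, fell. Of 20 MHC and antigen processing genes 2 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.452), with the class I gene H2-T23 at 1.31 and the immunoproteasome gene Psmb8 at -0.94. Of 24 T cell receptor complex and signalling genes 11 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.452), with Themis, a thymocyte selection gene, at -1.67.

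Markers of other cell types rose more often than they fell after restimulation. Of 8 B cell genes 7 rose and 0 fell (camera adjusted p = 0.0613, and 0.0226 without ATRA replicate 2 or 0.0438 without ATRA replicate 3), with a summed level of at most 58.5 CPM in any restimulated library. Ms4a1, a B cell surface protein gene, had no counts in CTRL and stood at 2.68 ± 0.510 CPM in ATRA cells, at least 15.8-fold higher. Of 8 NK cell genes 5 rose and 1 fell (camera adjusted p = 0.0658). That list passed with the replicate block (adjusted p = 0.0477) and without CTRL replicate 3 (0.0226) or ATRA replicate 2 (0.0490). Its summed level was 384 to 536 CPM in CTRL and 1144 to 1202 CPM in ATRA libraries, with Gzma, which activated CD8+ T cells also express, rising from 403 ± 78.3 to 1057 ± 27.9 CPM and Itga2 from 10.2 ± 0.765 to 78.8 ± 8.37 CPM. Of 10 GL261-like genes 6 rose and 2 fell (camera adjusted p = 0.225), with Thbs1 at 7.53 (9.47 without CTRL replicate 3) and Igfbp7 at -3.40, and the summed level of that list was 97.3 to 105 CPM in CTRL and 118 to 123 CPM in ATRA libraries. Axl alone gave 70.4 to 75.0 CPM of it in CTRL and 74.8 to 81.3 CPM in ATRA libraries. Of 4 monocyte and macrophage genes 3 rose, among them Clec7a (2.97) and Cybb (at least 4.72-fold), at up to 2.13 ± 0.959 and 0.801 ± 0.173 CPM. Of 8 dendritic cell genes 1 rose and 4 fell (camera adjusted p = 0.460), with Cd74 at -1.03 and Batf3 at -3.48 (-4.09 without ATRA replicate 3). All these counts were the same adjusted over the list alone, and no erythroid gene passed the filter.

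**Figure D2:**
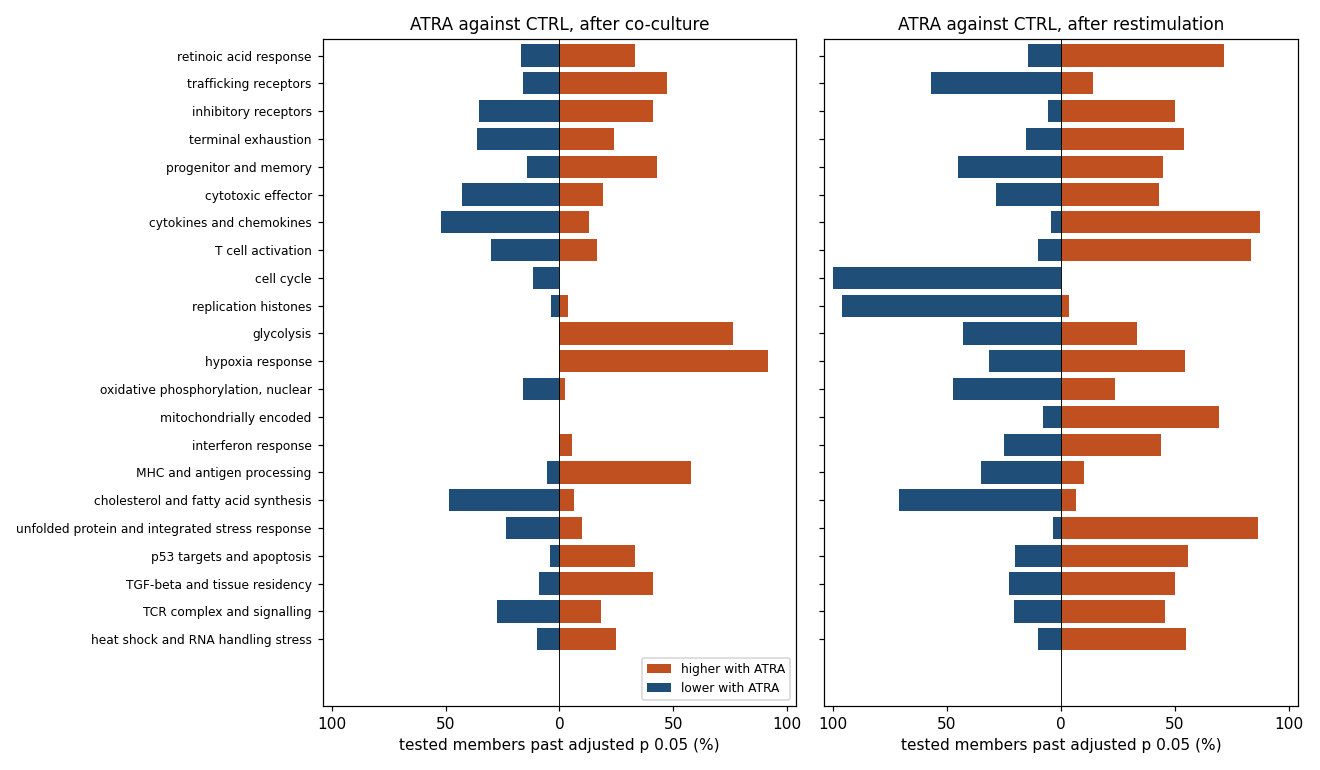
Share of the tested members of each of 22 fixed lists that passed an adjusted p of 0.05 in ATRA against CTRL libraries (3 against 3), before (left) and after restimulation (right); bars to the right count genes higher with ATRA and bars to the left genes lower with ATRA, in percent. After restimulation all 34 cell cycle genes were lower, and before it 22 of 24 hypoxia genes were higher.

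Whether the ATRA effect differed between the states was tested directly as an interaction, in which a positive value means a higher ATRA effect after restimulation. It differed for 6069 of 12359 genes, 2918 higher and 3151 lower. Scaling by library totals alone turned this balance to 3122 higher and 2834 lower. The fit takes 1 spread per gene for all 4 groups, although libraries varied more without restimulation. In such a fit the ATRA comparison without restimulation called 5792 genes, against 4071 from its own 6 libraries. The restimulated comparison called 6778, against 7998. The cytokine gene Il3 had the largest positive difference by the fixed rule (13.86, SE 0.52), followed by the growth factor gene Areg (11.87, SE 0.93), Ptprn (10.96, SE 0.32), Xcl1 (10.95, SE 0.37) and the collagen gene Col5a3 (10.68, SE 0.81). The largest negative differences were those of Cdh1, which encodes E-cadherin (-10.92, SE 1.28), Rasgrp2, an activator of the GTPase Rap1 (-7.85, SE 0.40), the chemokine receptor gene Cxcr4 (-7.71, SE 0.37) and Pygl, the liver glycogen phosphorylase gene (-6.96, SE 0.52). With 1 library left out, Il3 reached 14.59, Areg 11.17 to 13.03, Col5a3 12.51 and Cdh1 -9.30. Cxcr4 rose with ATRA from 9.11 ± 0.179 to 294 ± 127 CPM before restimulation and fell from 115 ± 8.03 to 18.0 ± 1.52 CPM after it. Sorcs2 was also called (adjusted p = 0.0272), with 1 group at 0, but not with the replicate block (adjusted p = 0.05005) or without CTRL replicate 3 of the restimulated cells (adjusted p = 0.99995).

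By list, 19 of 24 cytokine genes had a higher ATRA effect after restimulation and 1 a lower effect, also adjusted over the list alone, and 21 of 30 activation genes a higher and 2 a lower effect, with 22 and 2 adjusted over the list alone. Of 29 unfolded protein and stress response genes 24 were higher and 1 lower, with 25 and 1 adjusted over the list alone, and of 22 cytotoxic effector genes 11 were higher and 2 lower, also adjusted over the list alone. Of 34 cell cycle genes 0 were higher and 21 lower, also adjusted over the list alone. Of 20 glycolysis genes 0 were higher and 15 lower, with 0 and 16 adjusted over the list alone, and of 24 hypoxia genes 3 were higher and 15 lower, also adjusted over the list alone. The lists were not tested as sets in this fit.

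Genes called in both ATRA comparisons went the same way about as often as opposite ways. Of 11356 genes tested in both, 2557 were called in both, 1246 with the same sign and 1311 with opposite signs. Higher in both were 655 genes against 632 for independent lists, lower in both 591 against 581, higher then lower 627 against 648, and lower then higher 684 against 566. Across genes, which are not independent replicates, log2 fold changes correlated weakly (Pearson r = 0.0963, Spearman rho = 0.0940). Tgm2, Ndrg1 and Vegfa rose in both states, and Igfbp7 fell in both. Ifng, Xcl1, Prf1, Tigit, Egr2 and Crabp2 fell before and rose after restimulation, and Itga4 and S1pr1 rose before and fell after it. Without CTRL replicate 1 and ATRA replicate 3, an alternative added after the data were seen, 5074 genes were called in both, 2592 with the same sign and 2482 with opposite signs. Log2 fold changes across the 11377 genes tested in both then had Pearson r = 0.0124 and Spearman rho = 0.0211.

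**Figure D3:**
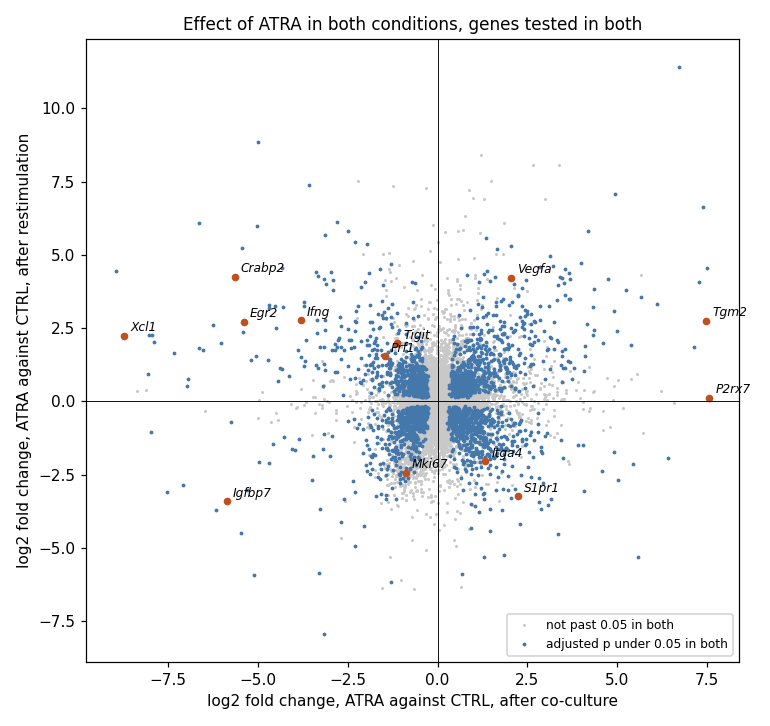
Log2 fold change of ATRA against CTRL before restimulation (x axis) and after it (y axis), each from 3 against 3 libraries; grey points are genes not called in both comparisons, blue points genes called in both, and orange points named genes. Of 11356 genes tested in both, 11335 are drawn, and 21 with a group at 0 in all libraries are left out; called genes lie in all 4 quadrants.

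The last comparison set restimulated control cells against control cells sorted right after co-culture, as background for the ATRA effects. State coincides here with batch set and with count table. No group was kept for 24 h without CD3e restimulation, so its effect cannot be told apart from that of the added time. Cytokine and activation genes were lower in the restimulated control cells. Ifng fell from 727 ± 110 to 56.7 ± 2.80 CPM, Tnf from 132 ± 20.6 to 32.8 ± 2.71 CPM, Prf1 from 743 ± 106 to 136 ± 11.1 CPM and Gzmb from 1376 ± 286 to 754 ± 46.2 CPM. Of 18 cytokine and chemokine genes 14 fell and 0 rose, with 16 and 0 adjusted over the list alone, and of 30 activation genes 27 fell and 0 rose, with 28 and 0 adjusted over the list alone. Of 34 cell cycle genes 32 rose and 0 fell, with 33 and 0 adjusted over the list alone, with Mki67 rising by 0.41. The integrin genes Itga4, Itgb7 and Itgae rose by 2.19, 2.13 and 3.76 and Slamf6 by 2.57, while Tigit (-1.65), Pdcd1 (-0.91) and Tox (-2.24) fell. Of 29 unfolded protein and stress response genes 26 fell and 0 rose (28 and 0 adjusted over the list alone), of 22 hypoxia genes 17 fell and 1 rose (18 and 1), and of 20 glycolysis genes 18 fell and 0 rose (18 and 0).

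In all, 4631 of 11645 genes were called, 2248 higher and 2383 lower, 1549 of them by at least 2-fold, and scaling by library totals alone gave 2843 higher and 1855 lower. The groups did not overlap for 6181 genes (53.1%), where chance gives 10%. By the fixed rule the largest changes were mainly in named pseudogenes, copies of ribosomal protein and Gapdh genes whose reads can be shared with the parent genes. Rps10-ps2, Rpl13-ps6, Rps18-ps5, Gapdh-ps15 and Rpl7a-ps5 were higher by 5.32 to 8.73. Rps12-ps3 stood at 592 ± 170 CPM in control cells without restimulation and at 0 in all 6 restimulated libraries, those of ATRA cells included. The annotation and counting behind each table are not given in the sources used here, so a difference in them cannot be told apart from a change in these pseudogenes. The same limit holds for every gene compared between the 2 states, in control and in ATRA cells. The other large decreases were those of Il23a, a subunit of interleukin 23 (-7.05), Vldlr (-6.68), Actbl2 (-6.54) and Tm4sf19 (-5.92). Without replicate 3 of the restimulated cells, Il23a, Vldlr and Tox stood at -7.81, -10.79 and -3.19, without replicate 1 of the other cells Rps10-ps2 stood at 11.17, and without their replicate 2 Rpl13-ps6 stood at 7.62. Lag3 fell by 1.01, a call that ended without CTRL replicate 1 (adjusted p = 0.0589) or 3 (adjusted p = 0.0533) of the cells without restimulation. Havcr2 (adjusted p = 0.0513), Il7r (adjusted p = 0.141), Entpd1 (adjusted p = 0.238), Dhrs3 (adjusted p = 0.102), Tcf7 (adjusted p = 0.741) and Rara (adjusted p = 0.420) did not pass. Without replicate 3 of the restimulated cells Havcr2 (-0.69, adjusted p = 0.0131), Entpd1 (-0.83, adjusted p = 0.00168) and Tcf7 (-2.69, adjusted p = 0.00419) passed. Without replicate 1 of the other cells Il7r (0.91, adjusted p = 0.00268) and Dhrs3 (2.97, adjusted p = 0.00471) passed, and without their replicate 3 Havcr2 (-0.61, adjusted p = 0.0477).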

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

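Of the tests reported here, those of exchanged treatment labels, ATRA replicate 3 and batch set for the opposite ATRA effects, of low depth, GL261 RNA and batch for ATRA replicate 3, and of the lower cytokine and activation genes in restimulated control cells were chosen only after the result was seen. The ATRA effect differed between the states for 6069 genes by the interaction test of edgeR, in which a positive value means a higher ATRA effect after restimulation. Among the genes named by the rule for the interaction, the difference was 13.86 for Il3, 11.87 for Areg, 10.96 for Ptprn, 10.95 for Xcl1 and 10.68 for Col5a3, and it was -10.92 for Cdh1, -7.85 for Rasgrp2, -7.71 for Cxcr4 and -6.96 for Pygl on the log2 scale. Among the genes fixed by name, those that differed upward were Ifng (6.58), Tigit (3.12), Prf1 (3.01), Pdcd1 (2.99), Havcr2 (1.75), Tnf (1.71), Lag3 (1.31) and Gzmb (0.61). Those that differed downward were Slamf6 (-5.25), Tcf7 (-4.24), Itgb7 (-3.43), Itga4 (-3.38), Itgae (-2.83), Mki67 (-1.56), Il7r (-1.22), Entpd1 (-1.18) and Rara (-0.97). The call of Tcf7 ended without any 1 of 7 libraries and with the replicate block (-3.35, adjusted p = 0.0591), and without CTRL replicate 3 of the restimulated cells its difference was -2.05 (adjusted p = 0.150). Gzmb lost its call without any 1 of 9 libraries (0.43 to 0.66, adjusted p = 0.0562 to 0.101) and with the replicate block (adjusted p = 0.0784). Itgae lost it without any 1 of 6 libraries (adjusted p = 0.0540 to 0.0638), and its difference was -1.44 without ATRA replicate 3 of the cells without restimulation. Among the others named, leaving out 1 library moved Il3 to 14.59, Areg to 11.17 or 13.03, Col5a3 to 12.51 and Cdh1 to -10.28 or -9.30. A further 74 of 99 genes named in the ATRA comparisons also differed, against 49.1% of all tested genes. Many of them were picked for a large change or a small p in the same libraries, which favours a difference. That count is therefore no added support. Sorcs2 is left out because 1 group was at 0. With 3 libraries per group, no test for single outlying values was applied.

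Before restimulation 12 of 23 cytokine genes and 9 of 30 activation genes were lower with ATRA and 3 and 5 higher, while after it 21 of 24 and 25 of 30 were higher, with a median difference of 3.21 over both lists. Exchanged treatment labels in 1 of the tables are argued against by Ccr9, a retinoic acid response gene, whose lowest level in any ATRA library was 40.0 CPM while all CTRL libraries of both states were at 0. ATRA replicate 3 of the cells without restimulation is argued against as the source, since the median difference without it was 2.97 (95% bootstrap interval over genes 1.76 to 4.06). Batch set stays open, because 0 batch sets hold libraries of both states, so batch and state cannot be told apart. A biological dependence of the ATRA effect on restimulation therefore remains a hypothesis.

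ATRA replicate 3 without restimulation stood apart from replicates 1 and 2. Low depth is argued against by its total of 26024194 counts, against 25149909 and 23558244. Without 12 abundant genes its higher correlation stayed at 0.962, below the 0.990 between replicates 1 and 2. These 12 genes are therefore argued against as the source of the lower correlation. Leaving out 12 genes can hardly move a correlation across all tested genes, so it does not show whether they themselves differed. RNA of the GL261 cells is argued against as the whole cause, since added RNA would keep T cell genes in their ratios to each other, but over 41 cytotoxic and T cell receptor genes the log2 ratios to replicates 1 and 2 had an SD of 0.63 (95% bootstrap interval 0.37 to 0.88), against 0.17 between replicates 1 and 2. As a source of the higher GL261 markers it stays open, although the sort for live CD45.2+ cells would remove glioma cells. The 17 markers under 5 CPM in replicates 1 and 2 summed to 23.1 CPM, against 9.55 and 9.42 CPM. Of these, 8 were at least 2 times higher and 4 lower than in both. Over all 20 listed genes present the sum was 102 CPM in replicate 3, against 105 and 96.7 CPM. The highest genes in that sum were Axl in replicates 1 and 2 (59.4 and 48.9 CPM) and Loxl2 in replicate 3 (39.3 CPM). Such high levels can hide a rise of the low markers, so the full sum does not decide. An effect of its batch that acted alike on both treatments is argued against by CTRL replicate 3 of the same batch, whose deviation had a slope of 0.0276 across genes (0.00401 to 0.0479) on that of ATRA replicate 3, where such an effect needs 0.841, whereas an effect on ATRA cells alone was not tested, and the design gives no biological explanation to test.

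Cytokine and activation genes were lower, not higher, in the control cells restimulated through CD3e, with medians of -2.75 over 18 cytokine genes (95% bootstrap interval -3.52 to -1.38) and -1.57 over 30 activation genes (-1.89 to -1.13). Gene by gene, the gap between the restimulation effects in ATRA and control cells is the difference of ATRA effects already described. It is therefore no separate evidence. A shift between the tables that is common to both treatments is argued against as the only difference by the ATRA cells. There the median was 0.13 (-0.25 to 1.46) over the same 30 activation genes, with 11 higher and 8 lower. It was 2.90 (1.70 to 4.96) over 24 cytokine genes. Some of these were not tested in control cells, since the filter admits genes high in restimulated ATRA cells alone, so the 2 cytokine medians cover unlike sets. A shift combined with a rise in ATRA cells stays open. Exchanged states in both treatments stay open as the direction differed by treatment, with 17 of 24 cytokine genes higher and 3 lower in restimulated ATRA cells. Exchanged states in the control libraries alone stay open too, because the correlation of restimulation effects between control and ATRA cells across 11370 other genes was 0.194 (0.130 to 0.264), which a shift between tables could give with or without an exchange. The restimulated state itself, after 72 h with antigen, remains a candidate explanation. Batch set and the added 24 h keep it from being told apart.

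Other splits of the libraries were counted for each model. In 1 of 10 splits as many genes were called as in the real one for ATRA without restimulation (4071), for ATRA with restimulation (7998) and for restimulated control cells (4631), and the highest count in any other split was 0 in each. The gene lists gave as many calls in 3 of 10 splits, both without restimulation (10 lists, highest other 11) and with it (15 lists, highest other 16). With 10 splits no share can go under 0.1, so the gene counts decide nothing. The number of called lists did not set the real split apart, since other splits reached 11 and 16 lists. Of the splits that part all 3 replicate pairs, the other ones called 0 genes and 9, 7 and 10 lists without restimulation, and 0 genes and 14, 6 and 7 lists with it, against 10 and 15 lists in the real split. For the difference between ATRA effects 1 of 100 pairs of splits gave as many genes as the real 6069 (highest other 3901), but the 100 disregard the pairing by replicate number. Only 16 of them part all 3 replicate pairs in both states, of which the real one gave the most genes (highest other 3901), and with 16 no share can go under 0.0625, so this count does not decide on chance either. For genes called in both comparisons 1 of 100 gave as many (2557, highest other 0), which decides nothing, because all other splits of either table called 0 genes.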

How the results depend on the processing

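The alternative without CTRL replicate 1 and ATRA replicate 3 of the cells without restimulation, and that without named pseudogenes, were chosen only after the data were seen. Every count of called genes stayed within 1.5 times its value except as follows, and the cause was not tested unless the construction shows it. Asking also for a 2-fold change, a stricter criterion by construction, left 1826 genes for ATRA without restimulation, 3287 with it, 3639 for the difference between them and 1549 for restimulated control cells. Leaving out 1 library gave 1613 to 5617 genes for ATRA without restimulation, where the counts without CTRL replicate 2 (1772), CTRL replicate 3 (1613) or ATRA replicate 2 (2226) moved, 7243 to 8184 with restimulation, 5353 to 7034 for the difference and 3286 to 5030 for control cells. Without both libraries that stood apart, whose removal narrows the spread, 7980 genes were called for ATRA without restimulation, 7454 for the difference and 5074 in both comparisons. Without named pseudogenes 4572 genes were called in control cells. Apart from the replicate block, other settings gave 3840 (library totals) to 5792 genes (all 12 libraries in 1 fit) without restimulation and 6753 (log2(TPM + 0.1)) to 8266 (no filter) with it. Upper-quartile scaling moved the balance without restimulation to 2560 higher and 1504 lower (63.0% against 53.7% higher).

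With an estimated correlation, 0 lists of 10 kept their call without restimulation and 4 of 15 with it, while fry, which tests the list against no other genes, called 14 and 22. Without both libraries that stood apart 13 lists were called before restimulation, with those of terminal exhaustion (adjusted p = 4.4e-05), memory (0.00689), activation (0.0463) and interferon genes (5.3e-21) gained and that of replication histones (0.0544) lost. For the interferon genes Isg20 and Rsad2 that removal also widened the group difference. Lists called ranged from 10 to 14 and from 13 to 17 when 1 library was left out. The replicate block gave 2892, 7752, 5395 and 4041 genes, 12 and 16 lists and 1785 genes in both comparisons. It ended the calls of Mki67, H4c9, H2ac6 and, for the difference, Sorcs2, Tcf7 and Gzmb, and added the activation, interferon and NK cell lists, and it changed no other call of a named gene or list.

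Of 444 values of named genes with 1 library left out before restimulation, 394 kept direction and call, 41 lost the call, 4 gained it and 5 turned direction; after restimulation these were 465, 4, 5 and 6 of 480. In the difference 301 of 324 values kept direction and call and 23 lost the call, and in control cells 172 of 180. All that turned were uncalled genes, with log2 ranges of -0.10 to 0.22 (Lag3), -0.27 to 0.11 (Gzmb) and -0.30 to 1.54 (Dhrs3) before, and -0.24 to 0.069 (Il7r), -0.56 to 0.71 (Tox), -0.13 to 0.085 (Pdcd1), -0.038 to 0.56 (Entpd1) and -0.018 to 0.24 (Itgb7) after restimulation. Pdcd1 also turned on log2(TPM + 1) (0.040), where Itgae lost its call (adjusted p = 0.0730). DESeq2 called Slamf6 (adjusted p = 0.0456) and Havcr2 (0.0383) before restimulation, Tcf7 (0.00271) after it, and Havcr2 (0.00986) in control cells. In the simulated counts, 27.9% of DESeq2 calls were unchanged genes before restimulation, 18.3% after it and 16.2% in control cells. With no filter the activation list before restimulation (0.0402), the B cell list after it (0.0317) and Havcr2 in control cells (0.0470) passed. No called named gene changed sign under another scaling, although before restimulation 2 lost their call with upper-quartile scaling and 1 lost and 1 gained it with library totals. In the ATRA comparisons the list medians of mitochondrially encoded, T cell receptor, CD4 T cell and B cell genes before restimulation and of glycolysis genes after it changed sign under 1 of these scalings, and scaling moved the median of all genes by at most 0.0952. At the depth of these libraries, 3 counts in the smallest correspond to 0.184 CPM, which limits statements on genes at 0.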

Other observations

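The comparison of restimulated with other ATRA cells and the comparison of ATRA replicate 3 with the ATRA effect were chosen only after the data were seen. In ATRA cells 6897 of 12000 genes were called after restimulation, 3406 higher and 3491 lower, in edgeR's quasi-likelihood test of 3 against 3 libraries. State coincides there with batch set, count table and 24 h of added time. Ifng had a log2 fold change of 2.80, Il3 of 8.55, Xcl1 of 8.02 and Egr2, a target of T cell receptor signals, of 4.89, while Tnf did not pass (-0.40, adjusted p = 0.415). Of 24 cytokine and chemokine genes 17 rose and 3 fell, with 18 and 3 adjusted over the list alone. Of 20 glycolysis genes 19 fell and 0 rose, 19 of 24 hypoxia genes fell and 1 rose, and 21 of 31 cholesterol and fatty acid genes fell and 2 rose, each also adjusted over the list alone, while of 33 nuclear oxidative phosphorylation genes 11 rose and 13 fell, also adjusted over the list alone. The lists were not tested as sets in this comparison. Pdk1, a kinase that inhibits pyruvate dehydrogenase, stood at -3.30. Of 32 interferon response genes 16 fell and 0 rose, and of 19 MHC and antigen processing genes 13 fell and 2 rose, also adjusted over the list alone. Of 34 cell cycle genes 9 fell and 1 rose (3 and 0 adjusted over the list alone), with Mki67 at -1.13.

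In control cells, lists not yet described moved in several directions after restimulation. Of 19 trafficking receptors 11 rose and 2 fell, also adjusted over the list alone. Of 25 terminal exhaustion genes 15 fell and 1 rose (18 and 1 adjusted over the list alone), of 32 interferon genes 14 fell and 1 rose (16 and 1), of 31 cholesterol and fatty acid genes 18 fell and 2 rose (20 and 2), and of 22 T cell receptor genes 13 fell and 2 rose (13 and 2). For the difference of ATRA effects, 11 of 26 terminal exhaustion genes were higher and 4 lower, 8 of 18 inhibitory receptors higher and 3 lower, 6 of 23 progenitor and memory genes higher and 11 lower, and 1 of 20 trafficking receptors higher and 8 lower, each also adjusted over the list alone. Of 27 replication histone genes 1 was higher and 13 lower (1 and 15 adjusted over the list alone), and of 20 MHC genes 1 was higher and 11 lower (1 and 12).

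ATRA replicate 3 without restimulation had summed NK cell markers of 1118 CPM, against 480 and 597 CPM in the other ATRA libraries of that state and 1144 to 1202 CPM in the restimulated ATRA libraries. Its CD4 T cell markers summed to 221 CPM, against 101 and 123 CPM and 220 to 228 CPM. Of these sums, Gzma, which activated CD8+ T cells also express, gave 1085 CPM and Gata3 126 CPM in this library. Ifng, however, stood at 9.61 CPM in it, against 77.3 and 67.7 CPM in replicates 1 and 2 and 384 ± 4.92 CPM (SD, n = 3) in restimulated ATRA cells. Its deviation from replicates 1 and 2 correlated weakly across 12111 genes, which are not independent replicates, with the ATRA effect measured in the others (Pearson r = 0.0678, Spearman rho = 0.189), a measure biased downward because replicates 1 and 2 enter both sides. Erythroid markers summed to at most 1.05 CPM in any library.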
